A study of Homo sapiens with 6 samples.

How the data were processed

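Polyadenylated RNA of single H9 cells from cysts was measured by a modified Smart-seq2 protocol, per the labels' protocols, with about 30 cysts pooled per time point, live cells sorted into 96-well plates, 23 cycles of PCR and single-end reads of 75 bp on a NextSeq instrument. Per the submitters' processing notes, the tools Trim Galore 0.5.0, HISAT2 (version not given in the sources used here) and featureCounts 1.6.1 were used and the builds GRCh38.p13 and hg38 are named, without their settings or which build served which samples. The deposited values are raw counts of reads per gene symbol and cell, with no molecular identifiers, for 394 cells and 59367 symbols, of which 55821 were found in GENCODE 29, the annotation used here for coordinates on GRCh38. Each cell's day, experiment and cell type were taken from the authors' deposited annotation, which the labels call batch for the experiment, and the method of cell type assignment is not given in the sources used here. Cell names were joined without regard to letter case. The cells came from 5 plates, and days 0 and 2 of experiment 1 shared a plate.

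Cells were kept with at least 50000 reads on genes, at least 2000 genes and at most 25% of reads on mitochondrially encoded genes, limits set before the data were examined together with the groups, tests, gene lists and named-gene rule. The mitochondrial limit was read as covering the 13 mRNA genes after totals had been seen, because all 37 mitochondrial genes, with ribosomal RNA, would have kept 40 cells. Of 394 cells, 265 were kept, while 110 fell under the read limit, 5 under the gene limit and 18 over the mitochondrial limit, with some cells past more than 1 limit. Median reads per kept cell were 143155.5, 271412 and 198083 at days 0, 2 and 4 of experiment 1 and 114535.5, 430047.5 and 84230.5 at days 0, 2 and 6 of experiment 2. No doublet caller was run, since cells were sorted singly into wells, and clusters were not computed because the authors' cell types were used.

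Cells are not replicates, so counts were summed over the kept cells of each sample, and 19593 genes passed the low-count filter of edgeR (filterByExpr). Differences between days were tested with edgeR 4.0.16 quasi-likelihood tests (limma 3.58.1, R 4.3.3) on all 6 samples with scaling by the trimmed mean of M-values (TMM) and Benjamini-Hochberg adjustment at 0.05, which gives all adjusted p-values printed for single genes. The model held days alone, except that days 4 and 6, each in 1 experiment, were compared with an experiment term. The alternative with experiment as a block was given beside the results because the labels mark experiments as batches, and the deviations of the samples from their day means correlated at 0.570 across genes between days 0 and 2 of the same experiment. The biological coefficient of variation was 0.873 for days alone and 0.514 with the experiment term, on 2 and 1 residual degrees of freedom. The prior degrees of freedom were 8.55 for days alone and infinite with the experiment term, so that in the latter the spread of each gene was taken wholly from the trend over genes. Gene lists were tested with camera at a preset correlation of 0.01, and Benjamini-Hochberg adjustment ran over all lists and comparisons. With an estimated correlation 0 list calls held. That setting gave weaker p-values in simulated counts as well. The simulated genes were drawn independently of each other, so whether low power or correlation among list genes left 0 calls is not shown. In simulated counts, a list of 30 genes changed 4-fold at day 4 against day 0 had an unadjusted camera p of 0.00858 for days alone and 0.0708 with the experiment term. At the preset correlation these were 3.97e-21 and 3.34e-15.

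The 34 gene lists held 708 genes, of which 705 matched by symbol and 3 by an older symbol. Lists can share members, as with GATA6 in the primitive streak and nascent mesoderm lists, so calls of such lists are not separate results. No call in either model was made for 12 lists, which covered actomyosin, apical polarity and lumen, endothelial and haematopoietic, HOX, naive pluripotency, neural crest, neuroectoderm, p53 and apoptosis, primed pluripotency, primordial germ cell, TGF-beta pathway component and unfolded protein response genes. Named genes were the 32 tested genes of a panel of 34, for each list with a call or 3 members past the threshold the 2 largest rises and 2 largest falls past it, and for each comparison the 8 largest rises and 8 largest falls past it with a mean of 20 CPM or more in the higher day, detection in 10% of its cells in each sample and the same direction in each experiment. LDHA, OCLN, MARVELD2, ID3, HAS2, TRIM27, RPS18 and TAPBP fall outside that rule and were named after their values were seen. Shares of positive cells were the cells with 2 or more reads after thinning each kept cell to 50000 reads (seed 1), with exact Clopper-Pearson intervals. Folds within an experiment are ratios of normalised levels with exact counting intervals, and a sample with no reads was set to a floor of 3 reads per library.

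The models were tested on simulated data, with 100 genes changed 4-fold and 100 changed 16-fold in each comparison, on 17429 to 17712 genes. For days alone, 0 of the 16-fold genes were recovered in each of the 5 comparisons fitted that way. With the experiment term, 90, 69, 72, 69, 74 and 37 of the 16-fold genes were recovered for day 2 against 0, day 4 against 0, day 6 against 0, day 4 against 2, day 6 against 2 and day 6 against 4, with 28, 7, 8, 10, 8 and 1 of the 4-fold genes and at most 3 calls among unchanged genes. DESeq2 made up to 33 calls among unchanged genes with days alone and up to 20 with the experiment term. The simulated counts had experiment differences that were the same on each day, and the spread of the trend over genes in the fit with the experiment term. As that fit assumes both, its few calls among unchanged genes do not measure its error rate on the real data.

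Alternatives were DESeq2 1.42.0, other scalings, no low-count filter, cells thinned to one depth, limma on mean log2(CPM/10 + 1), no cell filter, mitochondrial genes left out, each sample left out in turn and the replicate block. After the data had been seen, alternatives without the cells annotated Spont.Diff.2D, with the limit over all mitochondrial genes, without genes near 0 in 1 experiment, and with the block combined with another choice were added. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for cell shares and figures. Lists of read file names were not used.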

Results

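Single cells of H9, an established human embryonic stem cell line, were profiled while they grew as cysts in a basement membrane gel, a culture model of the human epiblast. The days compared address how epithelial identity, which the study relates to TGF-beta signalling, changed during growth of the cysts. Full-length cDNA was made from the polyadenylated RNA of sorted live cells in 96-well plates, and reads per gene were deposited for 394 cells in 6 samples. Experiment 1 held days 0, 2 and 4, and experiment 2 held days 0, 2 and 6. Days 0 and 2 therefore had 2 samples each, and days 4 and 6 had 1 sample each and no replicate check. In experiment 1 days 0 and 2 shared a plate, and each other sample had its own. Except between those 2 samples, a difference between days within an experiment is thus also one between plates. All samples were grown in the same medium, and no treatment arm was part of the design. After filtering, experiment 1 kept 36 of 46 cells at day 0, 32 of 43 at day 2 and 43 of 70 at day 4. Experiment 2 kept 54 of 82 cells at day 0, 62 of 70 at day 2 and 38 of 83 at day 6. Reads assigned to genes in the kept cells numbered 5727141, 8176000 and 11707901 at days 0, 2 and 4 of experiment 1. They numbered 7896796, 35330034 and 4345580 at days 0, 2 and 6 of experiment 2. Levels below are counts-per-million values scaled by the trimmed mean of M-values (CPM), and all 95% intervals and floors of 3 reads per library cover counting error only, because amplified reads without molecular identifiers are not independent molecules. The labels differ on the last day of experiment 2, which the sample title gives as day 6 and the growth protocol as day 5, and the title is followed here.

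The cell types that the authors assigned shifted with the day and also with the experiment. Cells annotated PSCs made up 85.4% of the 82 day 0 cells of experiment 2 (exact Clopper-Pearson 95% interval 75.8 to 92.2%) and 34.8% of the 46 day 0 cells of experiment 1 (21.4 to 50.2%). At day 2 of experiment 2, 27.1% of 70 cells were annotated Transition1 and 58.6% Transition2 (46.2 to 70.2%), and PSCs had a share of 8.57%. At day 6, 95.2% of 83 cells were annotated Post.EpiLike (88.1 to 98.7%). All 27 cells annotated Mes came from day 4, where they were 38.6% of 70 cells (27.2 to 51.0%), beside 24.3% PSCs and 21.4% Post.EpiLike. Cells annotated Spont.Diff.2D were 43.5% of the day 0 cells (28.9 to 58.9%) and 69.8% of the day 2 cells (53.9 to 82.8%) of experiment 1, and none of the day 0 or day 2 cells of experiment 2, which allows a share of up to 3.66% and 4.29% by a limit of 3 counts of the total. Shares were not tested between days, since each sample gives 1 value.

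**Figure D1:**
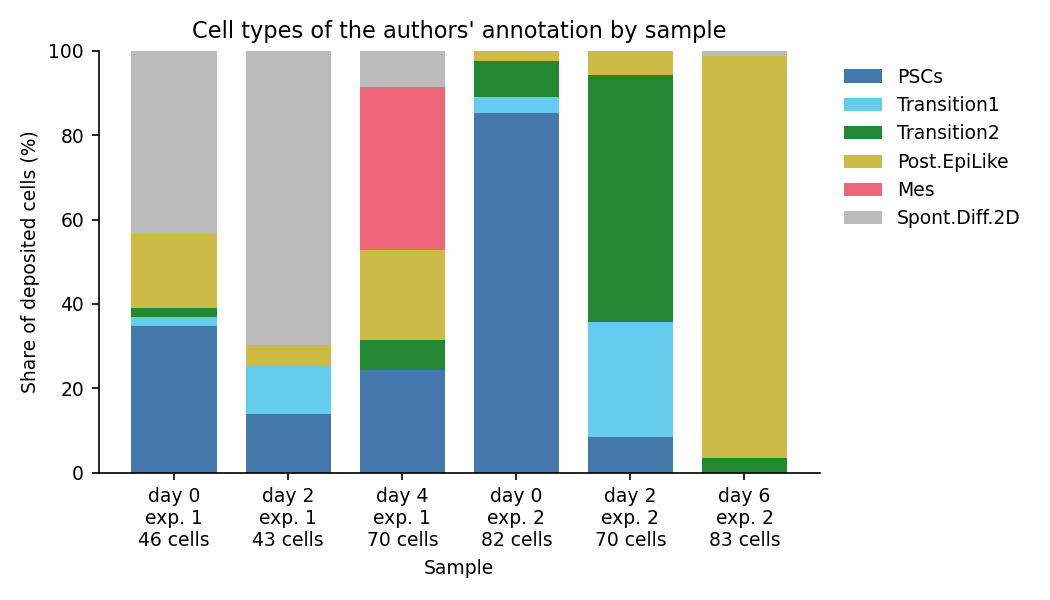
Stacked bars give the percentage of all deposited cells of each of the 6 samples that the authors assigned to each of 6 cell types, with the number of cells under each bar. Mes (38.6%) stands in the day 4 bar alone, and Post.EpiLike fills 95.2% of the day 6 bar.

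The samples parted first by experiment. The first principal component held 50.3% of the variance and separated the experiments, and correlations across genes were 0.819 to 0.933 within an experiment and 0.697 to 0.774 between experiments (genes are not independent replicates). At 50000 reads per cell, a median of 3869.5, 3165.5 and 4423 genes were detected at days 0, 2 and 4 of experiment 1, against 5902, 6015.5 and 6245.5 at days 0, 2 and 6 of experiment 2. Median shares of reads on mitochondrial mRNA were 14.1, 21.4 and 16.6% in experiment 1 and 1.84, 3.48 and 2.27% in experiment 2. POU5F1 (chromosome 6, 31164337 to 31180731, GRCh38, GENCODE 29), which encodes the pluripotency factor OCT4, stood at 0.385, 0.189 and 8.12 CPM at days 0, 2 and 4 of experiment 1 and at 46.2, 54.2 and 104 CPM at days 0, 2 and 6 of experiment 2. Its neighbours were low in the same samples: 23 protein-coding genes within 2 Mb of POU5F1 had a median log2 ratio of experiment 1 to experiment 2 of -3.81 at days 0 and 2, against -0.09 over 7059 protein-coding genes. In all, 108 genes stood at 1 CPM or less in every sample of experiment 1 and at 10 CPM or more in every sample of experiment 2, and 27 genes showed the opposite. The lactate dehydrogenase gene LDHA of the glycolysis list, the tight junction genes OCLN and MARVELD2 and the BMP target ID3 were among the former. LDHA had at most 0.385 CPM in experiment 1 and at least 1490.2 CPM in experiment 2.

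**Figure D2:**
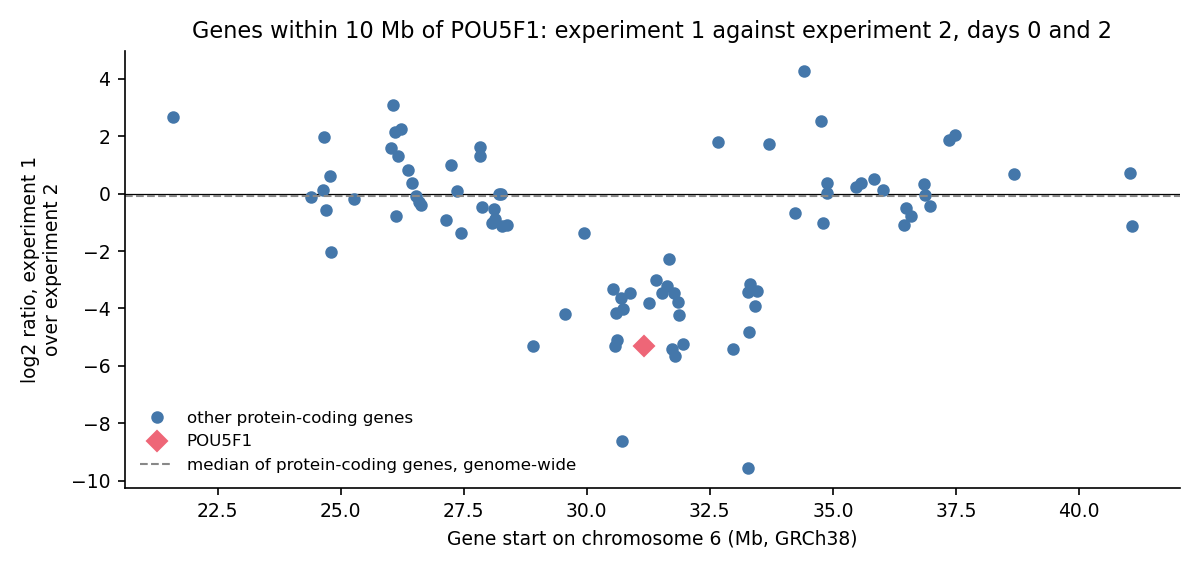
Each point is a protein-coding gene within 10 Mb of POU5F1, placed by its start on chromosome 6 (Mb, GRCh38), and the vertical axis gives its log2 ratio of experiment 1 to experiment 2 over days 0 and 2. The 23 genes within 2 Mb had a median of -3.81, and the 62 genes between 2 and 10 Mb away had a median of -0.03, although TRIM27 (-5.30), RPS18 (-9.56) and TAPBP (-4.83), just past 2 Mb, were low as well.

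Between days 0 and 2, GAL (chromosome 11, 68683779 to 68691175), which encodes the neuropeptide galanin, rose in each experiment. Its level went from 103 to 548 CPM in experiment 1 (5.34-fold, 95% interval 4.87 to 5.87) and from 7.25 to 44.1 CPM in experiment 2 (6.08-fold, 4.73 to 7.97). CCN2, a matricellular gene induced by YAP and by TGF-beta, fell from 498 to 10.8 CPM in experiment 1 (46.4-fold lower) and from 48.8 to 30.2 CPM in experiment 2 (1.61-fold lower). RORA, a nuclear receptor gene, fell 9.48-fold in experiment 1 and 4.46-fold in experiment 2. EOMES (chromosome 3, 27715949 to 27722711), a T-box factor of the primitive streak, had no read at day 0 and rose to 18.5 CPM in experiment 1 (at least 32.0-fold higher) and 1.38 CPM in experiment 2 (at least 3.93-fold higher). The edgeR quasi-likelihood fit with experiment as a block gave log2 changes of 2.51 ± 0.49 (SE) for GAL (adjusted p = 0.00128), -3.06 ± 0.62 for CCN2 (adjusted p = 0.0026) and -2.66 ± 0.54 for RORA (adjusted p = 0.0026) with n = 2 per day. EOMES, whose fitted size is not given because of its 0 reads at day 0, had an adjusted p = 3.55e-06. BCOR also passed (3.10 ± 0.62), but 1 cell held 91.8% of its reads in the day 2 sample of experiment 2.

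As groups, the YAP and TEAD target list and the hypoxia list fell from day 0 to day 2. Among 19 YAP and TEAD targets, 14 were lower and 1, CCN2, passed in the blocked fit (2 adjusted over the list alone), and the list had an adjusted p = 0.00478 (adjusted p = 0.959 with an estimated correlation). Of 21 hypoxia genes, 14 were lower and none passed singly (list adjusted p = 0.00145, and adjusted p = 0.959 with an estimated correlation), and without the cells annotated Spont.Diff.2D the blocked list p was 0.108 (median -0.49, from -0.89). Primitive streak genes rose with days alone in the fit (adjusted p = 0.0374) and not with the block (adjusted p = 0.160), and BMP targets behaved likewise (0.0444, and 0.0532 with the block or 0.0355 with the block and without the Spont.Diff.2D cells), each with an adjusted p = 0.959 with an estimated correlation for days alone. The block brought 5 further list calls, whose adjusted p = 0.992 with an estimated correlation. In it the 13 mitochondrially encoded genes rose (adjusted p = 0.000971, 5 members adjusted over the list alone), as did 33 oxidative phosphorylation genes (adjusted p = 0.00838, 29 higher), while glycolysis (adjusted p = 0.0331), G2/M (0.0446) and basement membrane and integrin genes (0.0412) fell. Cells annotated Spont.Diff.2D were 38.9% of the kept day 0 cells and 68.8% of the kept day 2 cells of experiment 1, and without them the blocked p was 0.0978 for the mitochondrially encoded list (median log2 change from 0.59 to 0.22), 0.571 for oxidative phosphorylation (0.38 to -0.08), 0.167 for glycolysis (-0.31 to -0.28) and 0.165 for basement membrane and integrin genes (-0.45 to -0.28). The G2/M list kept its call without these cells (blocked p of 0.00538, median from -0.24 to -0.35). Epithelial genes had no group call: the cadherin gene CDH1 (chromosome 16, 68737225 to 68835548) stood at 76.6 and 36.6 CPM at days 0 and 2 of experiment 1 and at 48.9 and 67.9 CPM in experiment 2. NODAL, which encodes a TGF-beta family ligand, did not pass (adjusted p = 0.575), with 2.69 and 59.0 CPM in experiment 1 and 0.468 and 0.911 CPM in experiment 2.

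With days alone in the edgeR quasi-likelihood fit, 0 of 19593 genes passed between days 0 and 2 (135 at an unadjusted p under 0.05), and DESeq2 and limma called 0 (230 and 24 unadjusted). With experiment as a block, 13 genes passed, 9 higher and 4 lower at day 2 (631 unadjusted), against 4 by DESeq2, 2 with library sizes alone (1 in each direction) and 0 by limma and with cells thinned to one depth. With days alone and all kept cells and samples, edgeR with the low-count filter and scaling used here passed no gene over all genes tested in any comparison (up to 47 with library sizes alone and 120 without the filter), so the single-gene calls named here come from the fit with experiment as a term. In that fit the p-values do not measure the spread between the 2 samples of a day, which the experiment term takes up. They rest on how far the change from day 0 to day 2 differed between experiments, with each gene's spread taken from the trend over genes. Nothing in the labels assigns the 2 samples per day to separate thaws or cultures beyond the experiment number.

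At day 4, genes of the primitive streak and early mesoderm stood far above day 0 within experiment 1. EOMES reached 112 CPM (at least 194-fold higher), APLNR (chromosome 11, 57233577 to 57237314), the apelin receptor gene of early mesoderm, 109 CPM (at least 189-fold), and the homeobox gene MIXL1 30.2 CPM (at least 52.3-fold). GATA6 (chromosome 18, 22169443 to 22202528), a mesendoderm factor, went from 0.385 to 53.6 CPM (139-fold, 38.4 to 1153.2), and CER1, a secreted inhibitor of NODAL and BMP, from 0.770 to 121 CPM (157-fold, 61.1 to 576). MESP1, a mesoderm factor, reached 23.4 CPM (at least 40.4-fold), and CYP26A1, a retinoic acid hydroxylase gene, 106 CPM (at least 184-fold). In the edgeR fit with the block, the adjusted p-values were 3.95e-12 for EOMES, 3.19e-15 for APLNR, 0.0304 for MIXL1, 0.000113 for GATA6, 3.7e-05 for CER1, 0.0478 for MESP1 and 5.69e-11 for CYP26A1. Levels of the same genes at days 0, 2 and 6 of experiment 2 were at most 1.38 CPM.

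**Figure D3:**
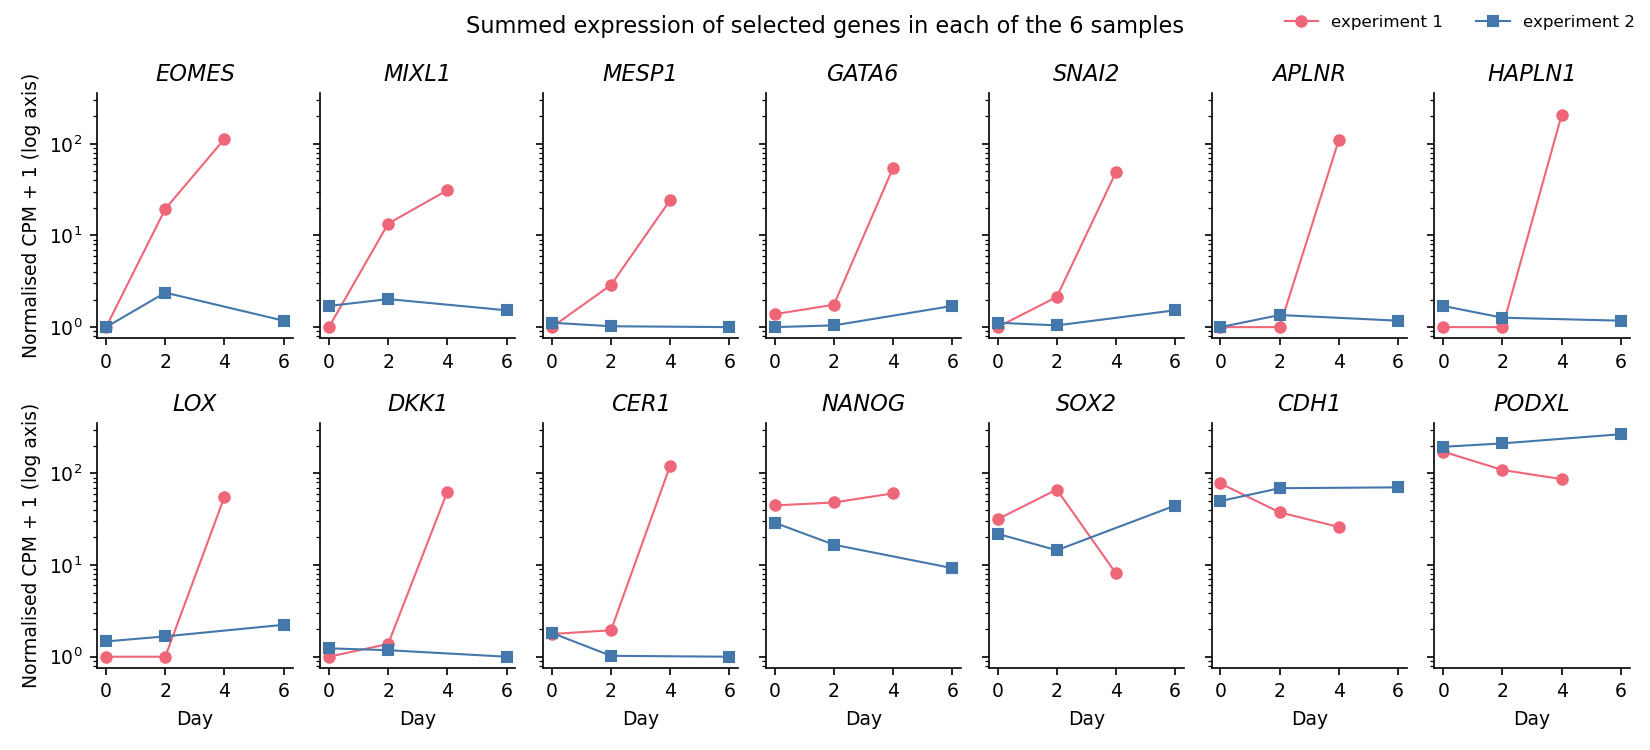
Each panel gives the level of 1 gene (normalised CPM + 1, log axis) by day, 1 point per sample, with circles and squares for the 2 experiments and lines joining the samples of an experiment. EOMES reached 112 CPM at day 4 of experiment 1, and stood at 0.176 CPM at day 6 of experiment 2.

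Each of the 20 tested nascent mesoderm genes was higher at day 4 than at day 0. The list rose (adjusted p = 1.11e-24 for days alone, and adjusted p = 0.959 with an estimated correlation), and 9 members passed adjusted over the list alone, or 9 over all genes and 15 over the list alone with the block. Primitive streak genes rose as a group (adjusted p = 3.60e-18, and adjusted p = 0.959 with an estimated correlation), with 8 of 17 higher and 1 lower past the blocked test and 9 higher and 1 lower for days alone, adjusted over the list alone. NKX1-2, a homeobox gene of the caudal epiblast and the 1 that fell, had 3 reads at day 0 and none at day 4 of experiment 1. Mesenchymal genes rose (adjusted p = 3.10e-10, and adjusted p = 0.959 with an estimated correlation), with 9 of 31 past the blocked test and 8 for days alone, adjusted over the list alone. Among them LOX, a collagen cross-linking enzyme, reached 54.6 CPM (at least 94.6-fold) and fibronectin, FN1, 64.6 CPM (7.81-fold, 5.74 to 10.9). For FN1, however, 1 cell held 83.7% of the reads at day 0 and 1 cell 40.4% at day 4 of experiment 1. SNAI2 (chromosome 8, 48917604 to 48921740), a repressor of epithelial genes, reached 48.1 CPM (at least 83.3-fold), with 77.9% of its reads in 1 cell. BMP targets (adjusted p = 7.77e-10, 3 of 15 past the blocked test) and TGF-beta, activin and NODAL targets (adjusted p = 5.93e-06, 4 of 26 higher and 1 lower) rose too, each with an adjusted p = 0.959 with an estimated correlation. Without the Spont.Diff.2D cells, the blocked p of the TGF-beta, activin and NODAL targets went from 0.0371 to 0.167, and their median log2 change from 1.28 to 1.09. The definitive endoderm (0.0660), WNT target (0.160), amnion (0.0987), trophoblast (0.0808) and immediate early (0.141) lists did not pass with the block, against adjusted p-values of 7.92e-06, 0.000312, 0.00433, 0.0221 and 0.0226 for days alone (adjusted p = 0.959 with an estimated correlation for each).

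Among 38 epithelial junction genes, the list did not pass between days 0 and 4. The keratin genes KRT8 (65.4 to 334 CPM, 5.11-fold, 4.57 to 5.73) and KRT19 (7.92-fold, 5.51 to 11.8) rose in the blocked fit (adjusted p = 0.00287 and 0.0183). CGN, which encodes the tight junction protein cingulin, fell (adjusted p = 0.00826), but 96.0% of its day 0 reads in experiment 1 came from 1 cell. CCN2 fell by 4.20 on the log2 scale (SE 0.73, adjusted p = 6.71e-06), and the metallothionein gene MT1G fell from 355 to 6.74 CPM (52.7-fold lower, adjusted p = 4.74e-07). IDO1, a tryptophan-degrading enzyme, fell from 79.1 to 1.57 CPM (50.4-fold lower, adjusted p = 9.11e-06). Oxidative phosphorylation genes passed with the block alone (0.235 for days alone). In it they fell (adjusted p = 3.19e-11, and adjusted p = 0.992 with an estimated correlation), with 4 of 33 lower past the test and 22 adjusted over the list alone, as in ATP5ME, an ATP synthase subunit gene (433 to 48.3 CPM, 8.97-fold lower). The Spont.Diff.2D share of kept cells in experiment 1 was 38.9% at day 0. Without these cells the list still passed with the block (adjusted p = 0.000158), and its median log2 change went from -1.59 to -0.61. The G2/M list fell with the block (adjusted p = 0.0209, and adjusted p = 0.992 with an estimated correlation). Without the Spont.Diff.2D cells its blocked p was 0.000697 (median from -0.47 to -0.51). POU5F1 rose in the blocked fit (4.80 ± 0.94, adjusted p = 0.000135) and was lower for days alone (-1.52), and it lies in the stretch of chromosome 6 with low reads throughout experiment 1.

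With days alone, edgeR called 0 genes between days 0 and 4 (472 at an unadjusted p under 0.05), DESeq2 84 and limma 0 (821 and 645 unadjusted). The block gave 334, of which 228 were higher and 106 lower. Library sizes alone changed that split to 127 and 18, and DESeq2 with the block to 117 and 147, while limma with the block called 60 higher and 0 lower and cells thinned to one depth gave 51 and 24. The median log2 change over all genes in the blocked fit was 0.17, or 0.37 with library sizes alone and 0.00 with DESeq2. The lone day 4 sample was assumed to vary like the samples of days 0 and 2.

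Within the day 4 sample, most of the mesoderm and epithelial genes named here were positive mainly in different annotated cells. At 50000 reads per cell, EOMES had 2 or more reads in 17 of 17 Mes cells and in 1 of 26 other cells, and APLNR in 14 and 0 cells. A count of 0 allows a share of up to 17.6% of the Mes cells and 11.5% of the others. HAPLN1, a hyaluronan link protein gene, was positive in 13 Mes cells and 0 other cells, and HAS2, a hyaluronan synthase gene, in 14 Mes cells and 1 other cell. EPCAM, an epithelial adhesion gene, was positive in 1 Mes cell and 17 other cells, CDH1 in 1 and 10, and PODXL, an apical sialomucin gene, in 0 and 17. NANOG, a pluripotency factor, was positive in 0 Mes cells and 15 other cells, whereas the DNA methyltransferase gene DNMT3B was positive in 9 and 14 cells. The intermediate filament gene VIM stood at 292 CPM of nuclear reads in Mes cells and 24.0 in the others. The N-cadherin gene CDH2 had 69.0 and 61.2, although 10 Mes cells and 2 other cells were positive. CER1 stood at 235 and 192, with 13 and 2 positive cells. FN1 stood at 127 and 101 and was positive in 3 Mes cells and 9 other cells. TBXT, the brachyury gene, was positive in 1 cell, and 98.2% of its day 4 reads came from 1 cell. Epithelial junction genes had a median log2 ratio of Mes to other cells of -1.76, with 20 of 25 lower, and mesenchymal genes one of 1.47, with 22 of 25 higher. The endoderm genes SOX17 and FOXA2 had no read in Mes cells and reads in 1 other cell each. No test was made, since the cells come from 1 sample and their types were assigned from the same transcriptomes.

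**Figure D4:**
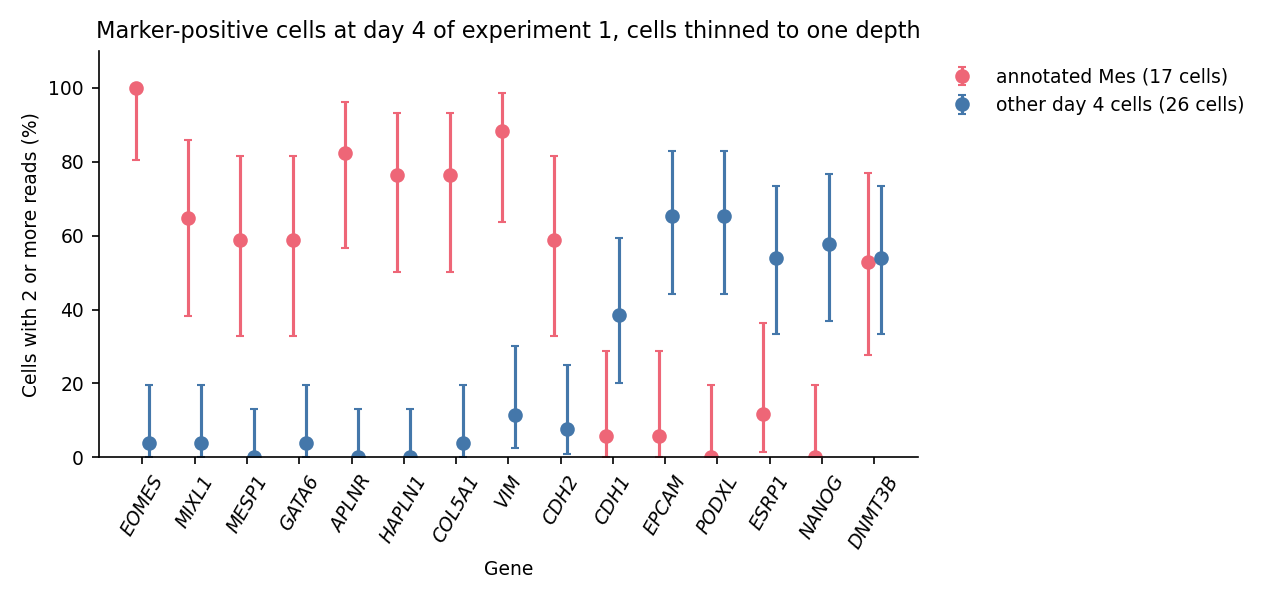
Points give the percentage of day 4 cells with 2 or more reads of each gene after every cell was thinned to 50000 reads, in 17 cells annotated Mes and 26 other cells, with exact 95% binomial intervals. EOMES was positive in 100% of the Mes cells and 3.85% of the others.

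Between days 2 and 4 of experiment 1, mesoderm genes rose and NODAL and SOX2 fell. APLNR (at least 193-fold higher, adjusted p = 2.52e-08) and HAPLN1 (chromosome 5, 83637805 to 83721613, at least 364-fold, adjusted p = 2.54e-22) had no read at day 2, though 65.9% of the day 4 reads of HAPLN1 came from 1 cell. CYP26A1 rose 282-fold (77.9 to 2332.1, adjusted p = 8.73e-12) and GATA6 71.1-fold (27.6 to 262, adjusted p = 0.0029). EOMES was 6.05-fold higher at day 4 (4.92 to 7.51) and did not pass (adjusted p = 0.0988). NODAL (chromosome 10, 70432315 to 70447951) fell from 59.0 to 0.554 CPM (107-fold lower, adjusted p = 0.000794), and SOX2 (chromosome 3, 181711924 to 181714436), a pluripotency and neural factor, from 65.6 to 7.11 CPM (9.24-fold lower, adjusted p = 0.0285). SOX2 was positive in 28.1% of day 2 cells and 6.98% of day 4 cells of experiment 1. NKX1-2 fell at least 75.6-fold (adjusted p = 0.000471) and GAL 5.55-fold (adjusted p = 0.0118).

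Nascent mesoderm (adjusted p = 3.66e-21, 10 of 20 past the blocked test), primitive streak (2.57e-12, 5 higher and 2 lower of 17), mesenchymal (2.79e-08, 7 of 31), BMP target (6.36e-06, 2 of 15) and TGF-beta, activin and NODAL target genes (0.000804, 1 higher and 1 lower of 26) rose as groups from day 2 to day 4, each with an adjusted p = 0.959 with an estimated correlation. Adjusted over the list alone, 9, 5, 4, 1 and 1 members were higher for days alone and 14, 12, 10, 5 and 3 with the block. GATA6 is in both the nascent mesoderm and primitive streak lists, so their calls are not separate results. Without the Spont.Diff.2D cells the blocked p was 0.133 for BMP targets (median log2 change from 1.71 to 0.92) and 0.347 for TGF-beta, activin and NODAL targets (1.05 to 0.59). Another 8 lists rose for days alone and not with the block: definitive endoderm (adjusted p = 0.000175), hypoxia (0.000666), WNT targets (0.00145), immediate early (0.00264), amnion (0.0137), FGF and ERK targets (0.0199), trophoblast (0.0326) and YAP and TEAD targets (0.0467), each with an adjusted p = 0.959 with an estimated correlation. Oxidative phosphorylation genes fell with the block (adjusted p = 7.55e-11, 13 of 33 past the test) and not for days alone (0.0504), and mitochondrially encoded genes fell with the block (0.00438, 3 of 13), each with an adjusted p = 0.992 with an estimated correlation. Without the Spont.Diff.2D cells, 68.8% of the kept cells at day 2 of experiment 1, the blocked p of these lists was 0.00284 and 0.334, and their median log2 changes went from -1.91 to -0.44 and from -0.75 to -0.15. Between days 2 and 4 edgeR called 0 genes for days alone (573 unadjusted), DESeq2 85 and limma 0 (1011 and 616 unadjusted), and with the block 515, of which 250 were higher and 265 lower. Library sizes alone changed that split to 104 and 22, and DESeq2 with the block to 169 and 334, while the median over all genes was 0.11, 0.39 and 0.00 in these 3 fits. With the block limma called 56 higher and 0 lower, and cells thinned to one depth gave 69 and 83.

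At day 6 of experiment 2, the mesoderm gene APLNR stood at 0.176 CPM and CER1 at 0 CPM. ZBTB18, a zinc finger repressor, rose from 0.935 to 77.4 CPM (82.8-fold, 41.6 to 193, adjusted p = 7.67e-06), and SP100, a nuclear body gene, from 129 to 689 CPM (5.35-fold, 5.00 to 5.72, adjusted p = 0.00245). EFNB2, an ephrin ligand gene, rose 21.3-fold (11.9 to 42.0, adjusted p = 0.0351). MSMO1 (chromosome 4, 165327623 to 165343160), a sterol oxidase of cholesterol synthesis, fell from 302 to 45.5 CPM (6.65-fold lower, adjusted p = 0.0098), and the cyclin-dependent kinase gene CDK1 (chromosome 10, 60778331 to 60794852) from 318 to 45.7 CPM (6.96-fold lower, adjusted p = 0.0215). CCN2 fell 5.34-fold (adjusted p = 0.00516).

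S-phase genes fell from day 0 to day 6 (adjusted p = 0.0226, 23 of 29 lower, none past the test singly), and mesenchymal genes rose (0.0496, 20 of 31 higher, none past the test), each with an adjusted p = 0.959 with an estimated correlation. Cholesterol synthesis genes fell with the block (adjusted p = 0.00904, 1 of 25 past the test and 5 adjusted over the list alone, against 0.277 for days alone), and immediate early genes rose (0.0209), each with an adjusted p = 0.992 with an estimated correlation. For days alone, oxidative phosphorylation (adjusted p = 2.02e-05), mitochondrially encoded (0.00625), G2/M (0.00726) and TGF-beta, activin and NODAL target genes (0.0153) fell and epithelial junction genes rose (0.0131), each with an adjusted p = 0.959 with an estimated correlation. With the block these lists did not pass (0.924, 0.0542, 0.195, 0.190 and 0.0504), the median log2 changes of the oxidative phosphorylation and mitochondrially encoded lists turned to 0.08 and 0.70, and without the Spont.Diff.2D cells the blocked p of the epithelial junction list was 0.0122. Median mitochondrial mRNA shares of 14.1% at day 0 of experiment 1 and 2.27% at day 6 of experiment 2 stood beside the mitochondrial differences. EdgeR called 0 genes for days alone (254 unadjusted), DESeq2 0 and limma 0 (535 and 1029 unadjusted), and 28 with the block, of which 18 were higher and 10 lower (2 and 0 with library sizes alone, 205 and 0 by limma, and no gene with cells thinned to one depth). The lone day 6 sample was assumed to vary like the samples of days 0 and 2.

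From day 2 to day 6, DDIT4, a hypoxia and stress inducible inhibitor of mTOR signalling, rose from 3.69 to 64.1 CPM in experiment 2 (17.4-fold, 14.4 to 21.0, adjusted p = 0.00039). The keratin genes KRT14 and KRT79 rose, KRT14 to 25.6 CPM (192-fold higher, 86.2 to 533, adjusted p = 0.0189) and KRT79 to 20.02 CPM (at least 300.3-fold, adjusted p = 0.00453). KRT17 stood at 24.8 CPM and its pseudogene KRT17P2 at 24.6 CPM, and whether reads of the gene were assigned to its pseudogene was not tested. ID1, a direct target of BMP signalling, fell from 26.9 to 2.81 CPM (9.56-fold lower, adjusted p = 0.0105), and its positive cells from 38.7 to 7.89%. SP100 rose 59.1-fold (53.9 to 64.8, adjusted p = 2.19e-07), and SERPINB9, a granzyme B inhibitor gene, fell 32.3-fold (adjusted p = 0.000656).

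As groups, hypoxia genes rose from day 2 to day 6 (adjusted p = 0.00299, 18 of 21 higher, 1 past the blocked test), as did glycolysis (0.00726, 20 of 21), epithelial junction (0.00149, 26 of 38, none past the test) and immediate early genes (0.0219, 20 of 24). LDHA of the glycolysis list and OCLN and MARVELD2 of the epithelial junction list were near 0 throughout experiment 1. S-phase genes fell (adjusted p = 0.00273, 23 of 29 lower) and core pluripotency genes fell (0.0371, 16 of 20 lower, none past the test), and each of these 6 lists had an adjusted p = 0.959 with an estimated correlation. Without the Spont.Diff.2D cells the blocked p of core pluripotency was 0.139, and its median log2 change went from -0.70 to -0.60. NANOG stood at 15.7 and 8.25 CPM at days 2 and 6 of experiment 2 and SOX2 at 13.5 and 43.5 CPM, and neither passed. Oxidative phosphorylation (adjusted p = 7.54e-07), mitochondrially encoded (0.000969) and TGF-beta, activin and NODAL target genes (0.00433) fell for days alone (adjusted p = 0.959 with an estimated correlation) and not with the block (0.119, 0.809 and 0.0666). Without the Spont.Diff.2D cells the blocked p of the TGF-beta, activin and NODAL targets was 0.0258. FGF and ERK targets (0.00624) and mesenchymal genes (0.0331) rose with the block alone (adjusted p = 0.992 with an estimated correlation, against 0.0592 and 0.154 for days alone). EdgeR called 0 genes for days alone (305 unadjusted), DESeq2 2 and limma 0 (701 and 903 unadjusted), and 34 with the block, 25 higher and 9 lower (13 and 0 with library sizes alone, 191 and 0 by limma, and 1 gene with cells thinned to one depth).

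Days 4 and 6 come from different experiments, and their comparison carries an experiment term estimated from days 0 and 2. A difference between them is therefore not shown to be a change over time. Mesoderm genes were lower at day 6 than at day 4: APLNR had 109 CPM at day 4 and 0.176 CPM at day 6 (adjusted p = 5.13e-05), and HAPLN1 206 and 0.176 CPM (adjusted p = 8.35e-11). Their fitted sizes are not given, because the experiment term rests on samples of experiment 1 with 0 reads of both genes. CER1 (adjusted p = 0.000798), DKK1, a secreted WNT inhibitor gene (0.00258), and LOX (0.00177) were lower as well. SOX2 was higher at day 6, with 7.11 CPM at day 4 and 43.5 CPM at day 6 (4.04 ± 1.04, adjusted p = 0.0242), and so was ZBTB18 (8.68 ± 1.45, adjusted p = 8.43e-06). Nascent mesoderm genes were lower at day 6 (adjusted p = 2.06e-05, 3 of 20 past the test and 10 adjusted over the list alone), as were primitive streak (0.0353, 4 of 17), BMP target (0.00337, none of 15) and TGF-beta, activin and NODAL target genes (0.0101, 1 of 26). Epithelial junction genes were higher at day 6 (0.0353, 26 of 38 higher, none past the test), as were oxidative phosphorylation (1.24e-09, 2 of 33) and mitochondrially encoded genes (0.00433, 1 of 13), and each of these 7 lists had an adjusted p = 0.959 with an estimated correlation. Without the Spont.Diff.2D cells, the adjusted p was 0.0725 for primitive streak (median log2 change from -5.54 to -4.45), 0.0594 for BMP target (-3.01 to -3.20), 0.0581 for mitochondrially encoded (0.93 to 0.24) and 0.0478 for TGF-beta, activin and NODAL target genes (0.0562 for the last among the tests of the blocked fits), and the oxidative phosphorylation median went from 1.61 to 0.45. Without an experiment term the oxidative phosphorylation and mitochondrially encoded lists had the opposite direction (medians -0.89 and -2.96, adjusted p = 0.047 and 0.000789, and adjusted p = 0.992 with an estimated correlation). PODXL stood at 85.5 and 266 CPM and CLDN6, a claudin gene, at 15.2 and 96.2 CPM, and neither passed. In all, 143 genes passed, 66 higher and 77 lower at day 6 (1832 unadjusted), against 138 by DESeq2, 86 higher and 52 lower, and 0 by limma (2598 unadjusted). The median over all genes was -0.35, or -0.05 by DESeq2 and -0.46 with library sizes alone. Library sizes alone gave 3 higher and 18 lower, the fit without an experiment term called 0 genes, and summing cells thinned to one depth gave 4.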

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

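The comparison of directions between experiments was planned, and its difference was not tested. VIM, the gene of the intermediate filament vimentin, moved in opposite directions from day 0 to day 2, with a log2 ratio of -1.92 in experiment 1 (39.8 to 10.6 CPM) and 1.87 in experiment 2 (13.1 to 47.8 CPM).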

How the results depend on the processing

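The settings without Spont.Diff.2D cells, with the limit over all mitochondrial genes, without genes near 0 in 1 experiment, and with the block combined with another choice were chosen after the data had been seen. Among named genes, 304 log2 changes gave 4222 alternative values with the same direction and call, 357 that gained a call and 105 that lost one. Another 9 reversed direction where the main or the alternative value had a call, and 169 changed direction with no call in either. Except for day 6 against day 4, the main values came from the fit with days alone, where no gene passed. There the same call means no call in either, so these counts do not measure the stability of calls made with the block. Of the alternative shares of positive cells, 700 stayed within the interval of the main share and 152 moved. Days 4 and 6 have 1 sample each in different experiments, and the smallest library holds 4345580 reads, so rare transcripts are limited by depth. Cluster alternatives were not run because the authors' cell types were used, and the comparison of days 4 and 6 could not be fitted with a sample left out. Except where a value shows it, the cause was not tested.

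Experiment as a replicate block gave 13 genes for day 2 against day 0, 334 for day 4 against day 0, 28 for day 6 against day 0, 515 for day 4 against day 2 and 34 for day 6 against day 2, each against 0 for days alone. For day 6 against day 4, no replicate block gave 0 against 143. The block changed no list call beyond those given with the comparisons. With DESeq2 and the block, 4 genes passed for day 2 against day 0. Among the 334 and 515 genes called with the block at day 4, 211 and 415 were also called by DESeq2 with the block. In the order of the 5 comparisons above, the replicate block gave 0, 75, 0, 152 and 1 genes with cells thinned to one depth, 2, 1.5e+02 (127 higher and 18 lower), 2, 126 and 13 with library sizes alone, 0, 60, 205, 56 and 191 with limma on mean log values, and 6, 127, 6, 112 and 16 without Spont.Diff.2D cells. With all deposited cells, or without genes near 0 in 1 experiment, the block gave counts within 1.5 times of these 5 in all comparisons.

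With days alone, and with the experiment term kept for day 6 against day 4, no low-count filter gave 2, 120, 14, 117 and 30 genes in that order and 73 for day 6 against day 4. DESeq2 gave 84 for day 4 against day 0, 85 for day 4 against day 2 and 2 for day 6 against day 2, and library sizes alone gave 37, 47 and 1 for these and 21 for day 6 against day 4. The limit over all mitochondrial genes, which kept 40 cells, gave 4, 18, 2 and 11 for the same 4 comparisons. Without Spont.Diff.2D cells the count was 32 for day 4 against day 0, 22 for day 4 against day 2 and 32 for day 6 against day 4. For day 6 against day 4, cells thinned to one depth gave 4 and limma gave 0. Size factors of the DESeq2 type in edgeR gave 0 in each day-only comparison and 130 for day 6 against day 4. Fixed lists had 50 calls of 204, 40 with the replicate block, 40 without Spont.Diff.2D cells and 0 with an estimated correlation. Shares of positive cells of 50% or more numbered 32 sample and gene pairs, and 14 with at least 5 reads.

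Leaving out 1 sample left another model with fewer days replicated. For day 2 against day 0 counts ran from 0 to 54, with 10 without day 0 of experiment 1, 39 without day 0 of experiment 2, 9 without day 2 of experiment 1 and 54 without day 2 of experiment 2. In the same order the counts were 121, 10, 129 and 115 for day 4 against day 0 (0 to 129), 0, 92, 11 and 23 for day 6 against day 0 (0 to 92), 120, 103, 140 and 9 for day 4 against day 2 (0 to 140), and 26, 25, 0 and 163 for day 6 against day 2 (0 to 163). Without the day 4 or the day 6 sample, the remaining comparisons gave 0.

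The log2 change of POU5F1, Day 2 against day 0, reversed from 0.23 to -6.84 without day 2 of experiment 2 and was 6.12 without day 0 of experiment 2. It reversed from -1.52 to 4.80 for day 4 against day 0 and from -1.75 to 4.76 for day 4 against day 2 with the replicate block. The pseudogene FAUP1 reversed from -0.74 to 2.75 for day 6 against day 0 with the block. For day 6 against day 4 without the replicate block, ATP5ME went from 3.67 to -0.16, FAUP1 from 4.13 to -0.46, MT-ND3 from 2.67 to -0.91 and NDUFS5 from 2.72 to -0.55. HIST1H1C went from 4.39 to -1.20 with the limit over all mitochondrial genes.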

Other observations

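The tests of copies of POU5F1, of the other pluripotency genes, of day 2 between experiments, of doublets by the genes of possible partner cells, of POU5F1 at day 4, of SNAI2 alone and of RNA quality were chosen only after the results had been seen, as were the values 2 to 10 Mb from POU5F1 and the counts of neighbouring genes. At day 2 of experiment 1, genes of the NODAL pathway stood above their levels in experiment 2. NODAL had 59.0 CPM against 0.911 and its inhibitor gene LEFTY1 16.03 against 1.53, and these differences were not tested. For LEFTY1, 2 of 32 cells were positive in experiment 1 and 2 of 62 in experiment 2. In these samples 1 cell held 50.6% and 65.2% of its reads. LEFTY2 reached 32.2 CPM at day 4, where the Mes cells held 119 CPM of nuclear reads and the other cells 0.922, but 4 of 17 Mes cells were positive and 1 cell held 55.9% of its day 4 reads. MT1G and MT2A, which encode metal-binding metallothioneins, stood at 355 and 119 CPM at day 0 of experiment 1 and at 6.74 and 6.37 CPM at day 4. The immediate early gene FOS had 3.46 CPM at day 0 and 64.4 CPM at day 4 of experiment 1 (18.6-fold, 11.7 to 31.6).

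Within day 0 and day 2 of experiment 1, cells annotated Spont.Diff.2D had oxidative phosphorylation genes above the other cells of the same sample, with median log2 ratios of 1.63 (28 of 33 higher) and 2.05 (29 of 33). Epithelial junction genes had medians of -1.20 and -1.98 and targets of TGF-beta, activin and NODAL -1.91 and -2.67, against -0.69 and -0.79 over all genes. Low medians were not particular to these lists, since unfolded protein response genes had -2.32 and -2.26 and YAP and TEAD targets -1.40 and -2.34. No test was made, since each sample gives 1 value.

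POU5F1 was near 0 at days 0 and 2 of experiment 1, including cells annotated PSCs, where 1 of 13 and 0 of 6 cells had a read, against 46 of 47 and 6 of 6 in experiment 2. Assignment to its near-identical copies was argued against, since POU5F1 and its copies together reached 10.99% of experiment 2, and so was loss of the pluripotent state, since the other 17 core pluripotency genes had a median log2 ratio of 0.45 (quartiles -0.86 to 0.80). The 23 genes within 2 Mb had a median of -3.81 and those 2 to 10 Mb away one of -0.03, although TRIM27 (-5.30) and RPS18 (-9.56) just past 2 Mb were low too, but a loss of reads over this stretch throughout experiment 1 stayed open as the cause for POU5F1, since at day 4 of the same experiment 6 of 7 PSCs had a read of it and the sample 8.12 CPM, while TUBB of this stretch had at most 0.192 CPM in experiment 1. Among 101 protein-coding genes near 0 throughout experiment 1, 43 pairs were adjacent on the genome, against a median of 2 and a highest of 9 in 10000 random draws. A hypothesis that stays open is that the experiments were counted against different forms of the genome, since 2 builds are named, but the positions of alternate sequences were not analysed here.

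Primitive streak and mesoderm genes were present at day 4 of experiment 1 and low at day 6 of experiment 2. A few deep cells were argued against as the source of EOMES, MIXL1, GATA6, APLNR and SNAI2 as a set. At one depth, 18 day 4 cells had 2 or more of these 5 genes and the other 25 had none. By annotation, 100% of the 17 Mes cells had 2 or more, against 3.85% of the 26 other cells, but the types were assigned from the same transcriptomes. The top 3 cells held a mean of 62.9% of the reads of each gene (41.7 to 95.2%), but for SNAI2 alone, at 95.2%, a few cells may account for the level. Doublets were argued against with cells split by their reads and not by the annotation. The genes compared were NANOG, EPCAM, ESRP1, PODXL and DNMT3B, each positive in at least 50% of the 25 cells with none of the 5 genes. They were positive in 17.8% of pairs of cell and gene in the 18 cells with 2 or more of the 5, against 58.4%. The 95% interval of 10.5 to 27.3% treats pairs of the same cell as independent and is therefore too narrow. The 58.4% is raised because the genes were chosen in those same 25 cells. NANOG was positive in 0 of the 18 and 15 of the 25 cells, EPCAM in 2 and 16, ESRP1 in 3 and 13 and PODXL in 1 and 16. DNMT3B, with 10 of the 16 positive pairs, had similar shares (55.6 and 52.0%). The number of genes per cell, 1.17 times that of the other cells (4970 against 4239.5), lay between the bounds set for it and decided nothing by itself. Day and experiment cannot be told apart for days 4 and 6. At day 2, 9 primitive streak genes, of a list with 17 tested genes, were compared between experiments. Their median log2 ratio of experiment 1 to experiment 2 was 2.37, with 8 of the 9 higher in experiment 1. A change between days 4 and 6 therefore remains possible and untested apart from the experiment.

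Cells annotated Spont.Diff.2D were most frequent at days 0 and 2 of experiment 1. Low RNA quality may account for the annotation, since these cells detected at most 0.625 times the genes of the other cells at one depth, and their median mitochondrial ribosomal RNA shares were 29.7 and 32.5% against 10.5 and 10.1%. That share does not mark low quality by itself. Over all kept cells its median was 32.9% in Spont.Diff.2D and 40.1% in Post.EpiLike cells, which detected a median of 2688 and 5468 genes at one depth. The Spont.Diff.2D cells also had more reads than the other cells, with medians of 218206.5 against 120733.5 at day 0 and 333403.5 against 216036 at day 2. Differentiation into a germ layer, mesenchyme, neural crest or amnion stayed open: the highest median log2 ratio that both samples reached for such a list was -0.53, under the bound set in advance, but the mesenchymal genes behind it went both ways (5 of 15 higher at day 0 and 8 of 16 at day 2) while all genes had medians of -0.69 and -0.79, so that bound could not decide. Lists of 4 genes were higher in 1 sample each, neural crest at day 0 (0.61, 3 of 4 higher) and neuroectoderm at day 2 (0.83, 3 of 4 higher). Whether another state of the cells in the 2 experiments contributed was not tested.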
